A study of Mus musculus with 18 samples.

How the data were processed

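RNA was isolated with a column kit (RNeasy, which the labels write RNAeasy) and assessed by 260/280 absorbance, per the labels' protocols. Per the same protocols, 0.1 µg of total RNA went into a TruSeq Stranded Total RNA preparation. The deposited tables hold 1 file per library with gene counts, RPKM values and a width per gene. The deposited gene counts are whole numbers of reads per gene and not normalised. The submitters' processing notes name the aligner GSNAP and the build GRCm38. Versions, the annotation, the counting tool and its use of strand are not given in the sources used here. The RPKM values were computed by the authors from the deposited counts, the gene width and a library total larger than the sum of the gene counts, as the values of the deposited tables show. They were used here only to recover that total. The share of the total that lay outside gene counts was 11.7% to 15.6% in 17 libraries and 31.3% in 24 h withdrawal 2. Gene identifiers were matched to GENCODE M21, on GRCm38, where 52403 of 52636 (99.6%) had a symbol. Coordinates come from that annotation, 1-based. Because use of strand is not stated, overlapping and antisense genes were not told apart, and near-identical genes such as Lyz1 and Lyz2 are uncertain where reads could be split between them.

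Libraries were grouped by the treatment in their labels into 6 groups of 3. Total counts ran from 31509607 to 52030066 per library, and 16846 to 21528 genes had a count. Intervals and floors from counts cover counting error only. No files of the 18 libraries were left out. Within groups no pair of libraries was close to sampling noise (chi-square per degree of freedom 7.53 to 1206 over 18 pairs), so each was counted as 1 sample.

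Before the data were examined, the following was fixed. Genes were filtered with filterByExpr by group, which removed 36139, and 16497 were tested. Counts were scaled by TMM factors and tested with edgeR 4.0.16 (glmQLFit with robust estimation and glmQLFTest) in R 4.3.3, in 1 fit of all 18 libraries without covariates, with Benjamini-Hochberg adjusted p under 0.05 as the threshold in each of 12 comparisons. SE is the log2 fold change divided by the square root of F. CPM are counts on TMM-scaled library sizes from edgeR, given as mean ± SD. Gene lists of pathways and cell type markers were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01. Lists needed at least 5 tested genes, p-values were adjusted over the lists of a comparison, and the test was run again with an estimated correlation. The 29 lists were canonical Wnt targets, Wnt receptors, Wnt ligands and planar polarity, cell cycle, cholesterol and fatty acid synthesis, transitional epithelial state, YAP and TEAD, TGF beta, BMP, Notch, and FGF and ERK targets. They also covered the NF-kB and cytokine, interferon, and unfolded protein and integrated stress responses, p53 targets, hypoxia and glycolysis, immediate early and heat shock genes and mitochondrially encoded genes. The cell type lists held markers of alveolar type 2, alveolar type 1, club and secretory, ciliated, basal, neuroendocrine, mesenchymal, haematopoietic, endothelial and gastric or gut cells. Within a list, p-values were also adjusted over the list alone. The genes named were those with the largest log2 fold change among called genes with an average log2 CPM of at least 2, no overlap between the groups and a symbol that is not a provisional name (up to 6 higher and 6 lower, or 3 and 3 for the comparisons of ligands with CHIR). Up to 4 called members per list with the smallest p were added, and always Axin2, Lgr5, Nkd1, Notum, Fzd5, Fzd6, Sftpc, Hopx, Ager, Scgb1a1 and Mki67. Notum stayed at or below a mean of 1.10 CPM in each group and was called in none of the 12 comparisons over 18 or 14 libraries.

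Alternatives fixed at the same time were DESeq2 1.42.0, RLE and upper-quartile factors, no filter, a filter of 1 CPM in at least 3 libraries, and mitochondrial and ribosomal RNA genes left out. Further ones were fits of only the compared groups, the replicate number as a block, a test against a fold of 1.5, the 48 h baseline for the ligands, other fold limits for the genes changed by withdrawal, and leaving out each library in turn for the counts of genes and of withdrawal genes moved back. Leaving out each library in the list tests was added after the data were seen. Chosen after the data were seen were the limit of 0.96 on a library's median correlation with the others, below which 4 libraries lie, and the fit of the other 14 libraries, with the rule for named genes applied to it. So were a term for the 3 libraries with low Xist, limma voom with quality weights and the 48 h baseline without the 4 libraries. Genes named outside the rule, after their values were seen, were Xist, Ddx3y, Bpifa1, Scgb3a1, Reg3g, Malat1, Neat1, Gm26917, Ptprc, Col3a1 and Cdh5 for their levels per library, Bex2 for 48 h withdrawal against CHIR over 18 libraries, and Aqp3, Egfr, Cyc1 and Uqcrq. A gene that the rule would name is not reported here. The 3 libraries with low Xist were not tested against the rest.

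The test was checked on simulated counts drawn from the real means and library sizes, with 100 genes changed 2-fold and 100 changed 4-fold. The changed genes were taken only from those with a mean above 2 CPM over the libraries. Recovery of genes below that level was therefore not measured. Over 18 libraries it recovered 13 and 68 for 24 h withdrawal against CHIR with 4 false calls, among 16497 genes. It recovered 6 and 72 for 48 h withdrawal against CHIR with 3, and 7 and 64 for Wnt against 24 h withdrawal with 2. Over 14 libraries it recovered 90 and 99 for 48 h against 24 h withdrawal with 16 false calls, among 17433 genes. Apart from the changed genes, all simulated libraries shared the same mean profile. The 4 libraries below the correlation limit of 0.96 therefore did not stand apart in the simulation, and false calls from such libraries are not covered. In a simulated comparison of the FZD5 with the FZD6 agonist, camera called the shifted cell cycle list and 0 of the other lists. The simulated genes were drawn independently of each other, so this run could not show false list calls that arise from correlated genes.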

Results

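Gene expression was measured by RNA sequencing in cultured mouse lung cells that the labels call alveolar type 2, the surfactant-producing epithelial cells of the alveolus. The cells had been grown for 19 days with CHIR99201, as the labels spell it, a small molecule that the series calls a Wnt agonist (CHIR below). LGK974, an inhibitor of porcupine that blocks the secretion of Wnt ligands, was listed for every group. The 6 groups held 3 libraries each. They were control cells with CHIR, cells after 24 h or 48 h of CHIR withdrawal, and cells in which CHIR was replaced by Wnt, by an agonist of the receptor Fzd5 or by an agonist of the receptor Fzd6. Treatments lasted 8 to 12 h, and the labels say neither whether the control cells had CHIR throughout or were given it again nor how long the ligand-treated cells had been without it, so both withdrawal times served as baselines. The total count per library lay between 31509607 and 52030066, which puts the level of 3 counts between 0.0577 and 0.0952 CPM (counts scaled to library size). Of 52636 listed genes, 16497 passed the filter on low counts and were tested in 12 comparisons. The labels do not state whether the 3 libraries of a group came from separate cultures or animals, so p-values measure only the spread between these libraries, which may be technical.

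Sftpc, the surfactant protein C gene that marks alveolar type 2 cells (chromosome 14, 70520949 to 70524081, minus strand, GRCm38 with GENCODE M21 as for all positions here), took 3.95% to 5.63% of all gene counts in 14 of the 18 libraries. In CHIR 1, CHIR 3, FZD6 agonist 1 and 24 h withdrawal 2 it took 9.88%, 9.53%, 9.11% and 13.05%, so the mean of the CHIR group was 75850 CPM with an SD of 34000 (n = 3). These same 4 libraries had median correlations of 0.782 to 0.950 with the others, against 0.966 to 0.982 for the remaining 14. Scgb1a1, a secretoglobin of airway club cells (chromosome 19, 9083636 to 9087958, minus strand), reached 50.8 CPM in CHIR 3, 79.8 CPM in FZD6 agonist 1 and 38.6 CPM in 24 h withdrawal 2, and lay between 0.0882 and 0.947 CPM in the other 15 libraries. Further airway genes followed it in CHIR 3, FZD6 agonist 1 and 24 h withdrawal 2. Bpifa1 was at 85.2, 116 and 42.0 CPM there and at most 0.246 CPM elsewhere, Scgb3a1 at 23.8, 50.0 and 16.4 CPM against at most 1.13 CPM, and Reg3g at 26.5, 208 and 93.0 CPM against 0. Xist, the RNA that silences 1 X chromosome in female cells (X chromosome, 103460366 to 103483254, minus strand), had 1, 0 and 4 counts in these 3 libraries and 251 to 812 counts in the other 15. The Y-linked gene Ddx3y was at 62.7, 72.9 and 75.8 CPM in the 3 and at 34.9 to 45.8 CPM elsewhere. The 24 h withdrawal 2 library also held 4.13% mitochondrially encoded counts, against 0.271% to 0.718% in the rest, and 10.8% of its counts fell on Malat1, Neat1 and Gm26917. Markers of blood cells (Ptprc), fibroblasts (Col3a1) and endothelium (Cdh5) stayed close to 0 CPM in every library. Because these 4 libraries fall in the CHIR, 24 h withdrawal and FZD6 agonist groups, each comparison is given over all 18 libraries and again over the other 14. The 14-library values are an alternative chosen after the data were seen. They leave 1 library with CHIR, 2 with the FZD6 agonist and 2 of 24 h withdrawal. They test 17433 genes and assume that the lone CHIR library, CHIR 2, varies like the other groups. The 3 CHIR libraries differed from each other by a chi-square per degree of freedom of 380.3 to 501, against 7.53 to 74.3 within the WNT, 48 h withdrawal and FZD5 agonist groups. A 14-library comparison with CHIR is therefore one with CHIR 2, and its p-values do not cover the spread between CHIR libraries. The 14 libraries are also part of the fit of all 18, so genes called in the same direction by both fits are no independent support.

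**Figure D1:**
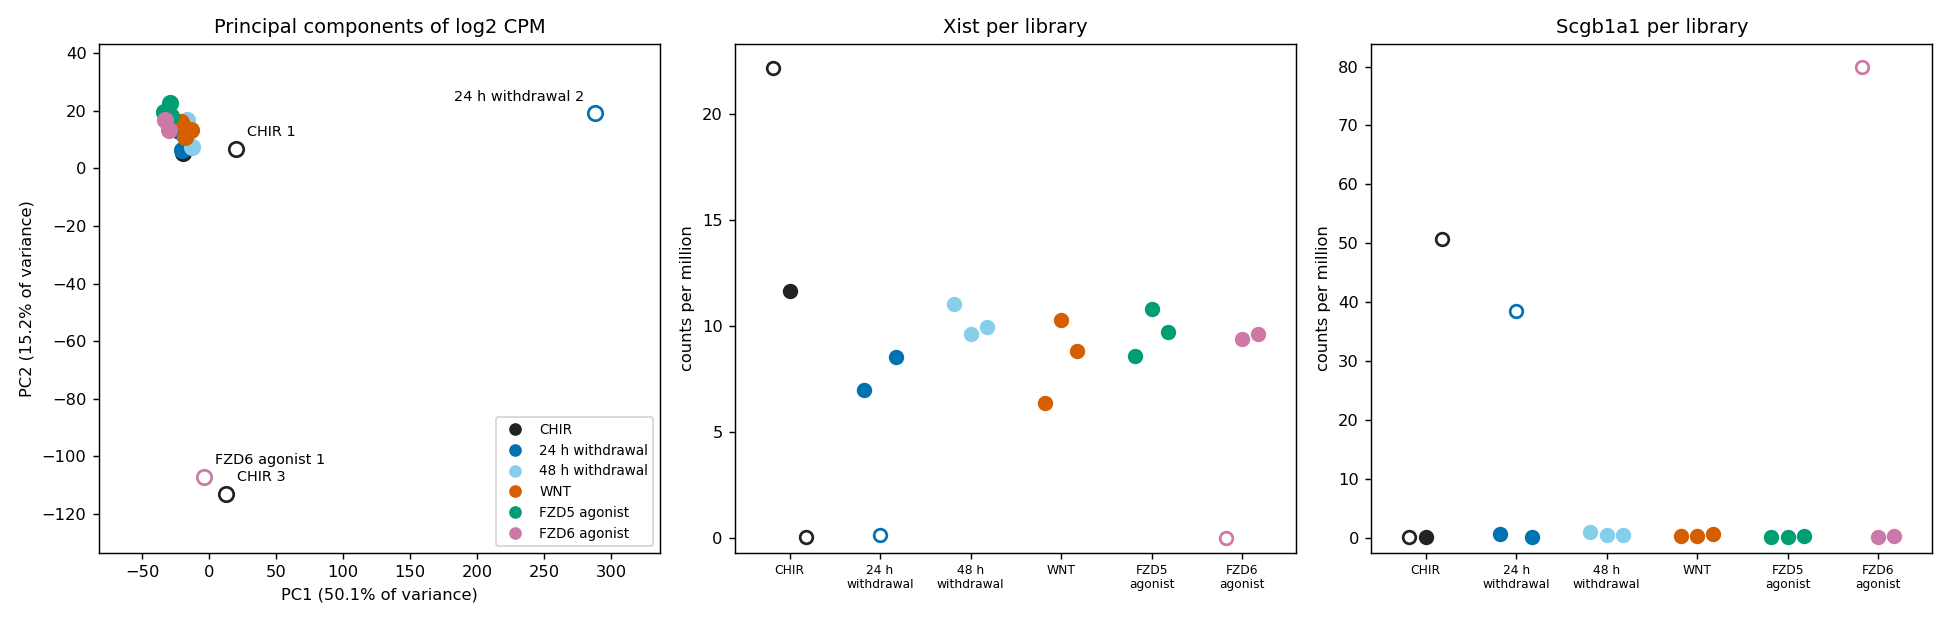
Left, the first and second principal components of log2 CPM over the 18 libraries, which hold 50.1% and 15.2% of the variance; middle and right, Xist and Scgb1a1 in CPM, 1 point per library. Open points are CHIR 1, CHIR 3, FZD6 agonist 1 and 24 h withdrawal 2, of which the last 3 have Xist at 0.0235, 0 and 0.141 CPM and Scgb1a1 at 50.8, 79.8 and 38.6 CPM.

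The comparison of 24 h withdrawal with CHIR asks what the first day without the Wnt agonist changed. Over all 18 libraries no gene passed the test. Axin2, a feedback inhibitor that is a standard readout of canonical Wnt signalling (chromosome 11, 108920349 to 108950783, plus strand), was at 2.38, 9.43 and 1.55 CPM in the CHIR libraries and at 2.20, 0 and 1.83 CPM after 24 h. Lgr5, a Wnt target and R-spondin receptor (chromosome 10, 115450311 to 115587780, minus strand), was at 7.74, 10.1 and 1.06 CPM with CHIR and at 1.17, 0 and 0.995 CPM after 24 h. Nkd1, an inhibitor of Wnt signalling that is itself a Wnt target (chromosome 8, 88521354 to 88594884, plus strand), averaged 22.8 ± 7.68 CPM after 24 h against 6.73 ± 2.00 CPM (log2 fold change 1.76, SE 0.40, edgeR adjusted p = 0.197). The alveolar type 1 genes Hopx and Ager averaged 124 ± 26.0 and 2065 ± 1537 CPM after 24 h against 51.0 ± 14.5 and 671 ± 305 CPM with CHIR (SD, n = 3 each), with edgeR adjusted p = 0.197 for both. All 30 cell cycle genes had lower fitted values, with a median log2 change of -0.71 (camera adjusted p = 0.00308; adjusted p = 0.955 with an estimated correlation). All 11 tested mitochondrially encoded genes were higher, with a median of 2.13 (camera adjusted p = 0.00308; adjusted p = 0.955 with an estimated correlation), and 10 were called when adjusted over the list alone. That last list moved with 24 h withdrawal 2, the library with 4.13% mitochondrial counts, without which its median was -0.11. The cell cycle call was also lost without 24 h withdrawal 2 (median -0.23), and also without CHIR 1 or CHIR 2. The alveolar type 1 list had 16 of 17 genes higher, 3 of them called when adjusted over the list alone (median 0.65, camera adjusted p = 0.0234; adjusted p = 0.955 with an estimated correlation). It lost its call without CHIR 1, CHIR 2, 24 h withdrawal 1 or 24 h withdrawal 3 (highest adjusted p = 0.477). The quasi-likelihood test of edgeR called 0 genes after Benjamini-Hochberg adjustment, and 2809 had an unadjusted p under 0.05. DESeq2 called 454 genes and limma voom with quality weights 0, while 8 were called without CHIR 3.

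Against CHIR 2 alone, Axin2 and Lgr5 were lower after 24 h over the 14 libraries. Axin2 averaged 2.02 ± 0.272 CPM (SD, n = 2) against 9.36 CPM in CHIR 2 (log2 fold change -2.21, SE 0.437, edgeR adjusted p = 0.0115), while CHIR 1 and CHIR 3, left out here, were at 2.38 and 1.55 CPM. Lgr5 averaged 1.08 ± 0.130 CPM (n = 2) against 9.97 CPM (log2 fold change -3.20, SE 0.690, edgeR adjusted p = 0.0227). The Wnt-responsive genes Tcf7 and Sp5 were also lower than in CHIR 2, by -2.54 and -0.70 on the log2 scale, while Nkd1 had a log2 difference of 1.69 (SE 0.603) and did not pass (edgeR adjusted p = 0.175). Of 19 Wnt targets tested, 0 were higher and 4 lower (1 and 5 when adjusted over the list alone), and the list as a whole did not pass (camera adjusted p = 0.104). Hopx and Ager were higher by 1.58 (SE 0.301) and 1.47 (SE 0.356), Napsa, an aspartic protease that processes surfactant proteins, by 1.49 (SE 0.275), and the caveola gene Cavin2 by 2.30 (SE 0.218). Of the 17 genes of the NF-kB and cytokine response, 1 was higher (Icam1) and 7 were lower, among them the chemokines Cxcl1 (-1.18, SE 0.176) and Cxcl5 (-0.72, SE 0.112). The list was lower with either correlation (median -0.63, camera adjusted p = 1.68e-05; adjusted p = 0.0227 with an estimated correlation). The cell cycle list had 7 of 30 genes lower, 22 when adjusted over the list alone (median -0.56, camera adjusted p = 7.05e-12; adjusted p = 0.329 with an estimated correlation). In all, 480 genes were higher and 304 lower by edgeR's quasi-likelihood test, with a single library standing for CHIR.

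After 48 h of withdrawal, alveolar type 1 genes such as Hopx and Ager rose relative to CHIR, and Asns, of the unfolded protein and integrated stress response list, fell. Both lists passed the test with the preset correlation and not with an estimated correlation (adjusted p = 0.110 for each). Hopx, a homeodomain protein of alveolar type 1 cells (chromosome 5, 77086988 to 77115121, minus strand), rose from 51.0 ± 14.5 to 240 ± 23.8 CPM (log2 fold change 2.23, SE 0.357, edgeR adjusted p = 0.00678, n = 3 each). Ager, the receptor for advanced glycation end products (chromosome 17, 34597862 to 34600936, plus strand), rose from 671 ± 305 to 2679 ± 144 CPM (log2 fold change 2.00, SE 0.455, edgeR adjusted p = 0.0300). All 17 alveolar type 1 genes were higher. Of these, 5 were called over all genes tested (Clic5, Cryab and Col4a3 with the former pair) and 13 when adjusted over the list alone (median 1.95, camera adjusted p = 1.72e-10; adjusted p = 0.110 with an estimated correlation). Of the 15 genes of the unfolded protein and integrated stress response, Asns, asparagine synthetase, fell from 452 ± 208 to 64.5 ± 4.17 CPM (edgeR adjusted p = 0.0102). Another 7 of these genes were lower when adjusted over the list alone (0 higher and 8 lower, median -0.72, camera adjusted p = 0.000104; adjusted p = 0.110 with an estimated correlation). Phgdh and Mthfd2, enzymes of serine synthesis and mitochondrial one-carbon metabolism, fell by 3.21 (SE 0.441) and 3.09 (SE 0.592) on the log2 scale.

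Canonical Wnt targets moved in both directions between CHIR and 48 h withdrawal. Nkd1 rose from 6.73 ± 2.00 to 51.9 ± 19.2 CPM (log2 fold change 2.95, SE 0.417, edgeR adjusted p = 0.00398). Bambi rose by 1.13 (edgeR adjusted p = 0.0138). Lgr5 fell to 0, 0 and 0.112 CPM in the 48 h libraries (edgeR adjusted p = 0.0241), and Sox9, a transcription factor of distal lung progenitors, fell from 2.80 ± 2.33 to 0.237 ± 0.231 CPM (edgeR adjusted p = 0.0445). Axin2 averaged 0.450 ± 0.304 CPM after 48 h against 4.46 ± 4.33 CPM and did not pass (log2 fold change -3.30, SE 1.04, edgeR adjusted p = 0.110). Of the 16 tested targets, 2 rose and 2 fell, 3 and 6 when adjusted over the list alone (camera adjusted p = 0.759). Wnt3a, a Wnt ligand (chromosome 11, 59248033 to 59290752, minus strand), had no count in any CHIR or 24 h library. It was at 1.02, 2.94 and 1.14 CPM after 48 h (edgeR adjusted p = 0.0397 against CHIR). With single libraries left out in turn, Wnt3a kept its call in 0 of 6 omissions (highest edgeR adjusted p = 0.119). Sox9 kept its call in 1 of them, Lgr5 in 2, Bambi in 3 and Nkd1 in all 6.

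Among genes past the level and overlap limits for naming, the steepest rises after 48 h were in Sec14l3, Mme, Rasl11b, Tuba8, Fam19a4 and Slc4a5, with log2 changes of 3.56 to 5.88. Sec14l3, a lipid-binding protein (chromosome 11, 4064841 to 4077736, plus strand), was at 90.3 ± 32.5 against 1.52 ± 1.19 CPM (log2 fold change 5.88, SE 0.957, edgeR adjusted p = 0.00762). The steepest falls were in Gdf15, Steap1, Fut1, Ly6a, Phgdh and Mthfd2. Steap1 (chromosome 5, 5736317 to 5749326, minus strand) went from 37.8 ± 13.4 to 2.47 ± 0.242 CPM (log2 fold change -3.93, SE 0.347, edgeR adjusted p = 0.000129). Among 22 alveolar type 2 genes, 3 rose (Chil1, Napsa and S100g) and 2 fell (Lyz1 and Bex2), 4 and 2 when adjusted over the list alone (median 0.62, camera adjusted p = 0.0145; adjusted p = 0.462 with an estimated correlation). Sftpc had a log2 change of -0.70 (SE 0.485, edgeR adjusted p = 0.523). All 30 cell cycle genes were lower, none called singly (median -1.21, camera adjusted p = 0.00999; adjusted p = 0.840 with an estimated correlation). Mki67, a proliferation marker, was at 58.9 ± 6.99 against 137 ± 106 CPM (edgeR adjusted p = 0.435). TGF beta targets (1 called, Pmepa1; 3 over the list alone; median 0.88) and BMP targets (2 called, Bambi and Atoh8; 4 over the list alone; median 1.05) were higher with camera adjusted p = 0.0049 and 0.00312, and with adjusted p = 0.473 and 0.280 with an estimated correlation. The club and secretory list did not pass (camera adjusted p = 0.191) and its test leaned upwards while its median was -0.25 and its mean -1.90, with CHIR 3 carrying these genes. In all, edgeR's quasi-likelihood test called 181 genes higher and 246 lower, DESeq2 1237 and limma voom with quality weights 1104. Without the 4 libraries 4791 were called against CHIR 2, 421 of the 427 among them in the same direction. The total was 57, 87 and 74 (32, 46 and 44 of them higher) without 48 h withdrawal 1, 2 and 3, 197 without CHIR 1 and 920 without CHIR 3. Of the 30 genes named for 48 h against CHIR and called, 10 kept their call in each omission (Sec14l3, Tuba8, Slc4a5, Steap1, Phgdh, Hopx, Cryab, Chil1, S100g and Nkd1). The cell cycle list lost its call without CHIR 1 or CHIR 2 (highest adjusted p = 0.578). So did the TGF beta list without CHIR 1 (adjusted p = 0.0748) and the alveolar type 2 list without CHIR 3 (adjusted p = 0.0600).

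In the 14-library fit, Axin2 was lower in the 3 libraries of 48 h withdrawal than in CHIR 2 by -4.37 on the log2 scale (SE 0.429, edgeR adjusted p = 3.99e-06) and Mki67 by -1.66 (SE 0.193, edgeR adjusted p = 5.31e-05). All 30 cell cycle genes were lower, with a median of -1.64 (camera adjusted p = 6.68e-20; adjusted p = 0.314 with an estimated correlation). Of the Wnt targets 3 were higher and 7 lower (median -0.78, camera adjusted p = 0.0511). The club and secretory list, in which 8 of 13 genes were higher, had a median of 2.94 (camera adjusted p = 4.49e-06; adjusted p = 0.0788 with an estimated correlation), led by haptoglobin (Hp, log2 fold change 5.91).

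**Figure D2:**
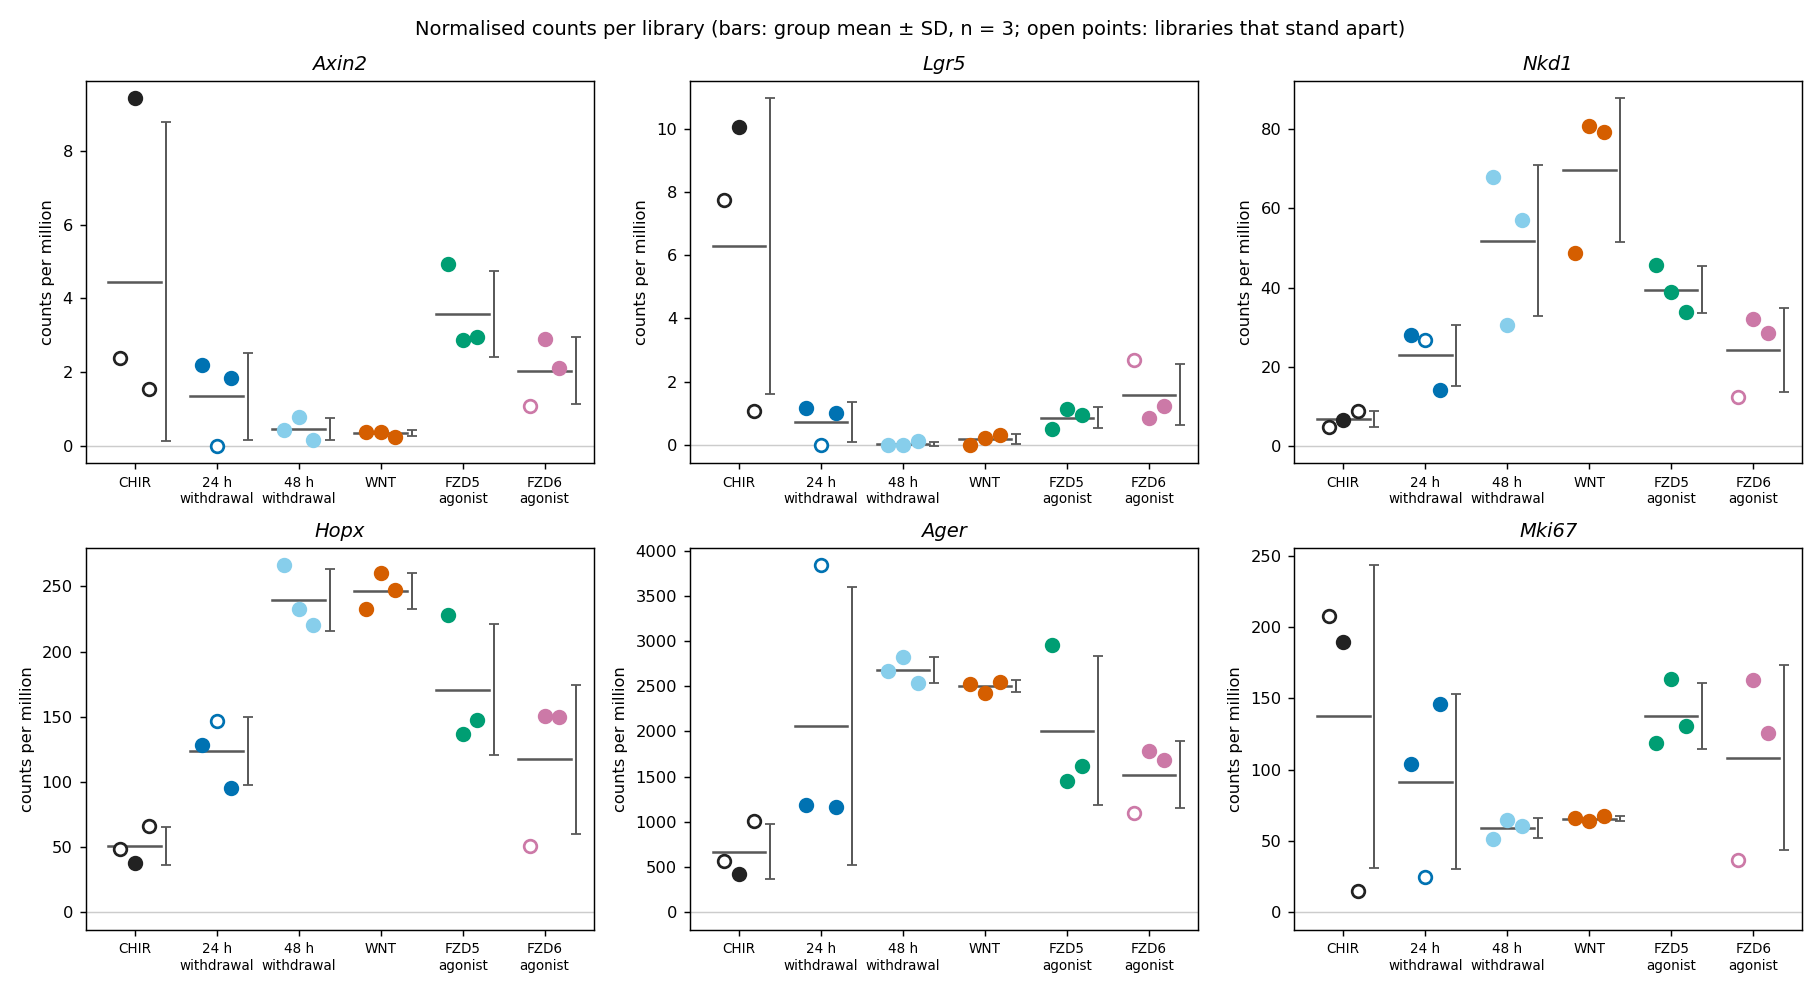
CPM of Axin2, Lgr5, Nkd1, Hopx, Ager and Mki67 in each of the 18 libraries by group, with the group mean (line) and SD (error bar, n = 3); open points are CHIR 1, CHIR 3, FZD6 agonist 1 and 24 h withdrawal 2. Axin2 lies between 0.167 and 0.771 CPM in the 48 h withdrawal and WNT libraries and between 2.88 and 4.94 CPM in the FZD5 agonist libraries.

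Between 24 h and 48 h of withdrawal 7 genes rose and 1 fell over all 18 libraries. Itih4, an inter-alpha-trypsin inhibitor heavy chain (chromosome 14, 30886476 to 30902353, plus strand), rose from 11.3 ± 5.48 to 107 ± 22.7 CPM (log2 fold change 3.24, SE 0.509, edgeR adjusted p = 0.0280, n = 3 each). Cxcl5, a neutrophil-attracting chemokine (chromosome 5, 90759360 to 90761624, plus strand), rose from 113 ± 19.8 to 304 ± 19.8 CPM, and Chil1, a chitinase-like protein of alveolar type 2 cells, from 5821 ± 1655 to 17740 ± 391 CPM. Itm2a, Cyp4v3 and Crebrf rose by 1.53 to 2.15 on the log2 scale, and Mettl1, a transfer RNA methyltransferase, fell from 15.8 ± 6.09 to 4.34 ± 0.818 CPM. The alveolar type 1 list rose further (16 of 17 higher, median 0.94, camera adjusted p = 2.39e-05; adjusted p = 0.373 with an estimated correlation). The unfolded protein and integrated stress response fell (7 lower over the list alone, median -0.66, camera adjusted p = 0.000957; adjusted p = 0.181 with an estimated correlation). Fatty acid synthesis genes were higher in 16 of 16 (median 0.47, camera adjusted p = 0.00186; adjusted p = 0.712 with an estimated correlation), a call lost without 24 h withdrawal 2 (adjusted p = 0.232). The mitochondrially encoded list, with a median of -2.41, turned to 0.48 without 24 h withdrawal 2. Of 8 genes called by edgeR's quasi-likelihood test, none was called without any 1 of the 48 h libraries and 1 without 24 h withdrawal 1. Without 24 h withdrawal 2, 12 genes were higher and 9 lower, and without 24 h withdrawal 3, which gives 24 h withdrawal 2 more weight, 49 were higher and 460 lower. DESeq2 called 565 and limma voom with quality weights 3289.

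Without the 4 libraries, Axin2 fell further between 24 h and 48 h, from 2.02 ± 0.272 (n = 2) to 0.454 ± 0.305 CPM (n = 3; log2 fold change -2.16, SE 0.411, edgeR adjusted p = 0.0021), and Mki67 fell by 1.07 (SE 0.163). The acute phase gene Hp rose from 35.7 ± 3.11 to 550 ± 69.5 CPM (log2 fold change 3.95, SE 0.160, edgeR adjusted p = 2.1e-08). Hopx and Ager rose by 1.11 (SE 0.213) and 1.19 (SE 0.257). Of 30 cell cycle genes, 24 fell (median -1.08, camera adjusted p = 3.26e-18; adjusted p = 0.321 with an estimated correlation). Of 17 genes of the NF-kB and cytokine response, 12 rose, 14 when adjusted over the list alone, among them Cxcl1, Tnfaip3 and Birc3 (median 0.70, camera adjusted p = 6.03e-10; adjusted p = 0.00258 with an estimated correlation). The chaperone Hspa5 fell by 0.83 (SE 0.0637) and Asns fell by 1.72 (SE 0.170), 2 of the 10 genes of the unfolded protein and integrated stress response that fell (median -0.76, camera adjusted p = 2.72e-08; adjusted p = 0.321 with an estimated correlation). A total of 1480 genes rose and 1656 fell, all 8 genes of the 18-library test among them in the same direction.

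Replacing CHIR with Wnt was compared first with 24 h withdrawal. Over all 18 libraries 5 genes rose and none fell, among them Itih4 (135 ± 16.7 against 11.3 ± 5.48 CPM, log2 fold change 3.58, SE 0.516, edgeR adjusted p = 0.0246, n = 3 each), Itm2a (2.16, SE 0.324), Cxcl5 (1.64, SE 0.227) and Cyp4v3 (1.59, SE 0.244). Axin2 was at 0.384, 0.373 and 0.238 CPM in the WNT libraries against 2.20, 0 and 1.83 CPM after 24 h and did not pass (log2 fold change -2.01, SE 1.01, edgeR adjusted p = 0.342). Nkd1 averaged 69.7 ± 18.2 against 22.8 ± 7.68 CPM (edgeR adjusted p = 0.216). Of the 17 genes of the NF-kB and cytokine response, 1 was called over all genes and 6 when adjusted over the list alone, and this list kept its call with either correlation (median 0.33, camera adjusted p = 0.00131; adjusted p = 0.0380 with an estimated correlation). It lost the call without 24 h withdrawal 1 or 24 h withdrawal 3 (highest adjusted p = 0.0661). The unfolded protein and integrated stress response was lower (6 over the list alone, median -0.64, camera adjusted p = 0.0014; adjusted p = 0.258 with an estimated correlation). The alveolar type 1 list was higher (median 0.71, camera adjusted p = 0.000389; adjusted p = 0.524 with an estimated correlation), both in each single omission. The 16 Wnt targets had a median of 0.18, a mean of -0.14 and no call (camera adjusted p = 0.177). The quasi-likelihood test of edgeR called 5 genes with all libraries, 21 without 24 h withdrawal 2 and 0 without any other 1 of the 6 libraries. DESeq2 called 374 and limma voom with quality weights 2403.

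With 14 libraries, Axin2 was lower with Wnt than after 24 h of withdrawal (0.338 ± 0.0821 CPM, n = 3, against 2.02 ± 0.272, n = 2; log2 fold change -2.56, SE 0.415, edgeR adjusted p = 0.000908). Lgr5 and Sox9 fell by 2.56 and 2.81 on the log2 scale, while Nkd1 rose by 1.76 (SE 0.418) and Bambi by 1.06 (SE 0.117). Of the Wnt targets 2 rose and 4 fell (median -0.49, camera adjusted p = 0.317). The chemokines Cxcl1, Cxcl2 and Cxcl5 rose by 1.60, 1.63 and 1.53, and 12 of 17 genes of the NF-kB and cytokine response rose (median 0.81, camera adjusted p = 3.51e-12; adjusted p = 0.00123 with an estimated correlation). Mki67 fell by 0.90 (SE 0.162), with 18 of 30 cell cycle genes lower (median -0.80, camera adjusted p = 1.53e-13; adjusted p = 0.548 with an estimated correlation). Hp rose by 3.92 (SE 0.159), Hopx by 1.16 (SE 0.213) and Ager by 1.11 (SE 0.256). There were 1176 genes higher and 1195 lower, the 5 genes of the 18-library test among them in the same direction.

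With 48 h withdrawal as the baseline, the WNT libraries did not differ by any called gene. The quasi-likelihood test of edgeR called 0 genes over 18 libraries and 0 over 14, with 35 and 1344 genes at an unadjusted p under 0.05. DESeq2 called 0 and limma voom with quality weights 1. Axin2 had a log2 difference of -0.40 (SE 0.451) over the 14 libraries. The hypoxia and glycolysis list was higher with Wnt (median 0.44, camera adjusted p = 4.37e-06; adjusted p = 0.849 with an estimated correlation). In the 14-library fit the cell cycle list was higher by a median of 0.27 with 0 genes called singly (camera adjusted p = 1.11e-09; adjusted p = 0.697 with an estimated correlation).

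Against 24 h withdrawal 1 gene was higher with the FZD5 agonist over all 18 libraries, Cxcl5, at 363 ± 34.7 against 113 ± 19.8 CPM (log2 fold change 1.69, SE 0.227, edgeR adjusted p = 0.0299, n = 3 each). Cxcl5 was also at 304 ± 19.8 CPM after 48 h without a ligand and at 350 ± 15.1 CPM with Wnt. With the FZD5 agonist Axin2 was at 4.94, 2.88 and 2.95 CPM (log2 fold change 1.41 against 24 h withdrawal, SE 0.963, edgeR adjusted p = 0.485). With the FZD6 agonist no gene passed, and Axin2 was at 1.09, 2.90 and 2.12 CPM (log2 fold change 0.59, edgeR adjusted p = 0.767). The receptor genes themselves, Fzd5 (chromosome 1, 64730558 to 64737751, minus strand) and Fzd6 (chromosome 15, 39006034 to 39038188, plus strand), were at 9.36 ± 0.902 and 51.4 ± 34.1 CPM after 24 h of withdrawal. Fzd6 was at 12.5 CPM in 24 h withdrawal 2 and 48.1 to 86.6 CPM in the other libraries. Of the 16 Wnt targets, 14 had higher fitted values with the FZD5 agonist (median 0.63, camera adjusted p = 0.0125; adjusted p = 0.560 with an estimated correlation). All 16 had with the FZD6 agonist (median 0.57, camera adjusted p = 0.00938; adjusted p = 0.754 with an estimated correlation), with 0 called singly in either. Both calls were lost without 24 h withdrawal 2 (adjusted p = 0.296 and 0.168). The same omission ended the cell cycle call of the FZD5 agonist, whose 30 genes were all higher (median 0.51, camera adjusted p = 0.000814; adjusted p = 0.562 with an estimated correlation; adjusted p = 0.774 without 24 h withdrawal 2). Cholesterol synthesis genes were higher with the FZD5 agonist in each omission (median 0.43, camera adjusted p = 0.00329; adjusted p = 0.560 with an estimated correlation), as was the alveolar type 1 list (median 1.17, camera adjusted p = 7.7e-05; adjusted p = 0.560 with an estimated correlation). The alveolar type 2 list was higher with either agonist in each omission (medians 0.35 and 0.46, camera adjusted p = 0.0125 and 0.00938; adjusted p = 0.560 and 0.754 with an estimated correlation). For the FZD5 agonist edgeR's quasi-likelihood test called 0 genes without 24 h withdrawal 1 or any 1 of the agonist's own libraries, 3 without 24 h withdrawal 2 and 1139 without 24 h withdrawal 3, of which 54 were higher and 1085 lower. DESeq2 called 145 and limma voom with quality weights 326. For the FZD6 agonist it called 0, with 2517 genes at an unadjusted p under 0.05, DESeq2 233 and limma voom with quality weights 131. It called 609 without 24 h withdrawal 1 (12 higher and 597 lower), 985 without 24 h withdrawal 3 (28 and 957), and 1 without 24 h withdrawal 2 or FZD6 agonist 1.

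In the 14 libraries, genes of the NF-kB and cytokine response rose with both agonists against 24 h withdrawal. This list also rose with Wnt and at 48 h without a ligand, so the rise was not particular to the agonists. Against 48 h withdrawal, Cxcl5 was higher by only 0.266 and 0.305 with the FZD5 and FZD6 agonists. Against 24 h withdrawal, Cxcl5 rose by 1.57 with the FZD5 agonist (SE 0.0900, edgeR adjusted p = 2.52e-07, n = 3 against 2) and by 1.61 with the FZD6 agonist (SE 0.0955, edgeR adjusted p = 4.18e-07, n = 2 against 2). Cxcl1 rose by 1.30 and 1.39, the NF-kB inhibitor gene Nfkbia by 0.75 and 0.67, and Nfkbiz by 0.88 and 0.82. Of the 17 genes of this list, 8 and 6 rose, 11 and 11 when adjusted over the list alone (medians 0.70 and 0.59, camera adjusted p = 3.01e-11 and 3.55e-13; adjusted p = 0.00149 and 0.000841 with an estimated correlation). The lysozyme gene Lyz2 rose from 706 ± 12.0 to 1656 ± 247 CPM with the FZD5 agonist (log2 fold change 1.23, SE 0.104) and to 2034 ± 3.19 CPM with the FZD6 agonist (1.53, SE 0.112). Itih4 rose by 2.44 (SE 0.185) and 2.24 (SE 0.193). Frrs1, Padi2, S100a6 and Ly6a fell, by 1.96, 1.79, 1.61 and 1.56 with the FZD5 agonist and by 1.76, 1.53, 1.52 and 1.30 with the FZD6 agonist. Over all 18 libraries Nfkbia, Padi2 and Ly6a had the other sign with the FZD6 agonist (-0.19, 0.72 and 0.65), none of them called. Fzd5 rose by 0.68 with the FZD5 agonist (SE 0.153, edgeR adjusted p = 0.0229). Among Wnt targets, Sp5 rose by 0.40 and 0.49, and Axin2 did not pass with either agonist (0.85, SE 0.360, edgeR adjusted p = 0.221, and 0.33, SE 0.391, edgeR adjusted p = 0.799). Nor did Nkd1 (0.94 and 0.55, edgeR adjusted p = 0.272 and 0.689). No cell cycle gene was called singly, and Mki67 had log2 changes of 0.16 and 0.22 (edgeR adjusted p = 0.691 and 0.679). With the FZD5 agonist 414 genes rose and 324 fell, and with the FZD6 agonist 93 rose and 25 fell, a difference in number that is not a test between the agonists.

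Against 48 h withdrawal, cells with either agonist had higher cell cycle genes over the 14 libraries, and Axin2 was compared here for the FZD5 agonist only. Axin2 was higher with the FZD5 agonist by 3.01 (SE 0.373). The cell cycle list rose with 27 of 30 genes called for the FZD5 agonist (median 1.13, camera adjusted p = 1.06e-22; adjusted p = 0.462 with an estimated correlation), and 30 of 30 for the FZD6 agonist (median 1.23, camera adjusted p = 6.89e-28; adjusted p = 0.305 with an estimated correlation). Of the Wnt targets 8 rose and 2 fell with the FZD5 agonist (camera adjusted p = 0.116) and 7 rose and 2 fell with the FZD6 agonist (median 0.47, camera adjusted p = 0.0459; adjusted p = 0.305 with an estimated correlation). Over all 18 libraries edgeR's quasi-likelihood test called 0 genes for the FZD5 agonist and 2 for the FZD6 agonist, against 2737 and 2118 over 14. The unadjusted p was under 0.05 for 393 and 667. DESeq2 called 23 and 61, and limma voom with quality weights 3387 and 3720.

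The agonists of Fzd5 and Fzd6 were compared with each other directly. No gene differed over all 18 libraries, and 1 over the 14, Zcchc14, a zinc finger gene (chromosome 8, 121598703 to 121652901, minus strand). It was at 31.7 ± 1.79 CPM with the FZD5 agonist (n = 3) and 16.9 ± 2.13 CPM with the FZD6 agonist (n = 2; log2 fold change 0.91, SE 0.119, edgeR adjusted p = 0.0225). Axin2 differed by 0.82 (SE 0.947) over 18 libraries and by 0.52 (SE 0.349) over 14, with an edgeR adjusted p = 1 for both. Over 18 libraries Hopx differed by 0.54, Ager by 0.40, Mki67 by 0.35, Fzd5 by 0.28 and Fzd6 by -0.03, none of which passed. The alveolar type 1 list was higher with the FZD5 agonist (16 of 17 genes, median 0.56, camera adjusted p = 5.89e-06; adjusted p = 0.611 with an estimated correlation). The club and secretory list was lower (median -1.24, camera adjusted p = 0.000887; adjusted p = 0.784 with an estimated correlation). Both calls were lost without FZD6 agonist 1 (adjusted p = 0.0907 and 0.995), the library with Scgb1a1 at 79.8 CPM. The p53 target call (median -0.32, camera adjusted p = 0.00525; adjusted p = 0.784 with an estimated correlation) ended there too, at an adjusted p = 0.995. Mitochondrially encoded genes were higher with the FZD5 agonist over 18 libraries (median 0.60, camera adjusted p = 0.0116; adjusted p = 0.784 with an estimated correlation), a call lost without FZD6 agonist 2 (adjusted p = 0.0973). They were also higher over 14 (median 0.54, camera adjusted p = 4.43e-11; adjusted p = 0.147 with an estimated correlation). The quasi-likelihood test of edgeR called 0 genes, with 164 at an unadjusted p under 0.05. DESeq2 called 0 and limma voom with quality weights 2. On simulated data for this comparison over 18 libraries, the test recovered 9 of 100 genes changed 2-fold and 66 of 100 changed 4-fold with 4 false calls, and over 14 libraries 89 and 95 with 16 false calls. The simulated libraries shared the same mean profile, so false calls from libraries that stand apart were not covered. Nor was recovery of genes with a mean below 2 CPM, since none of these was changed.

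Both agonists were then set against Wnt. Axin2, over the 14 libraries, was at 3.65 ± 1.22 CPM with the FZD5 agonist (n = 3) and 2.54 ± 0.554 CPM with the FZD6 agonist (n = 2) against 0.338 ± 0.0821 CPM with Wnt (n = 3). The log2 differences were 3.41 (SE 0.378, edgeR adjusted p = 3.84e-05) and 2.89 (SE 0.405, edgeR adjusted p = 0.000336). Lgr5 was higher by 2.27 and 2.52 and Sox9 by 2.60 and 3.18. Of the Wnt targets 8 were higher and 3 lower with the FZD5 agonist, and 8 and 2 with the FZD6 agonist (camera adjusted p = 0.261 and 0.109), Bambi being among the lower ones (-0.95 and -0.89). Nkd1 had log2 differences of -0.82 and -1.21 and did not pass (edgeR adjusted p = 0.155 and 0.0962). Mki67 was higher by 1.06 (SE 0.148) and 1.13 (SE 0.162), and 24 and 25 of 30 cell cycle genes were higher (medians 0.88 and 0.99, camera adjusted p = 3.58e-15 and 3.48e-22; adjusted p = 0.39 and 0.30 with an estimated correlation). Ctnnd2, delta-catenin, was higher by 3.25 (SE 0.163) and 3.26 (SE 0.171), Tmem132d by 4.37 and 3.93, Sema5a by 3.29 and 3.17, and Tgfb3 by 2.80 and 2.64. Hp was lower by -3.15 (SE 0.129) and -3.13 (SE 0.152), Retnla by -5.14 and -5.62, and Chil1 by -0.72 and -0.67. Over all 18 libraries no gene passed in either comparison (Axin2 3.42, SE 1.05, and 2.60). There the cell cycle list was higher with the FZD5 agonist in each omission (29 of 30 genes, median 0.88, camera adjusted p = 0.0011; adjusted p = 0.923 with an estimated correlation). The unfolded protein and integrated stress response was higher with the FZD6 agonist with either correlation (15 of 15 genes, 5 over the list alone, median 0.46, camera adjusted p = 5.83e-07; adjusted p = 0.0418 with an estimated correlation), though over 14 libraries only with the preset one (camera adjusted p = 1.6e-05; adjusted p = 0.367 with an estimated correlation). The same list was higher with the FZD5 agonist over 18 libraries (14 of 15 genes, median 0.39, camera adjusted p = 0.00797; adjusted p = 0.432 with an estimated correlation), a call lost without FZD5 agonist 2 (adjusted p = 0.0582). For the FZD5 and FZD6 agonists edgeR's quasi-likelihood test called 0 and 0 genes over 18 libraries, with 413 and 606 at an unadjusted p under 0.05 (2 for the FZD6 agonist without its replicate 3), and 2903 and 2057 over 14. DESeq2 called 30 and 58, and limma voom with quality weights 3513 and 3674. A fit of the FZD5 agonist and WNT libraries alone called 1998.

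Finally, each ligand group was compared with the CHIR control. With Wnt, Nkd1 rose by 3.37 (SE 0.424, edgeR adjusted p = 0.00352), Hopx by 2.28 (SE 0.357, edgeR adjusted p = 0.00815) and Ager by 1.90 (SE 0.453, edgeR adjusted p = 0.0441), while Steap1 fell by 3.49 (SE 0.340) and Asns by 2.78. In all, 144 genes were higher and 173 lower with Wnt. Of the 5 genes named here and called, Nkd1, Hopx and Steap1 kept their call in each omission. With both agonists Crebrf, a regulator of the CREB3 factor (chromosome 17, 26715650 to 26776635, plus strand), was the single gene called. It was at 32.3 ± 5.78 CPM with the FZD5 agonist (log2 fold change 2.04, SE 0.237, edgeR adjusted p = 0.00486) and 27.6 ± 3.63 CPM with the FZD6 agonist (1.81, SE 0.235, edgeR adjusted p = 0.0198) against 7.88 ± 2.54 CPM (n = 3 each). Crebrf was at 32.2 ± 3.54 CPM after 48 h of withdrawal without a ligand, so this level was not particular to the agonists. The alveolar type 1 list was higher in each omission with Wnt, the FZD5 agonist and the FZD6 agonist (medians 1.88, 1.78 and 1.20; 10, 16 and 7 genes over the list alone; camera adjusted p = 2.74e-09, 3.76e-12 and 1.96e-09; adjusted p = 0.152, 0.219 and 0.146 with an estimated correlation). The YAP and TEAD targets were higher with the FZD5 and FZD6 agonists in each omission (medians 1.15 and 0.91, camera adjusted p = 0.000425 and 2.92e-05; adjusted p = 0.304 and 0.162 with an estimated correlation). They were also higher with Wnt and at 48 h of withdrawal (medians 0.62 and 0.71, camera adjusted p = 0.0189 and 0.00732; adjusted p = 0.531 and 0.462 with an estimated correlation), calls lost without CHIR 1 (adjusted p = 0.20 and 0.0748). With the 14 libraries Axin2 was below its CHIR 2 level by -4.77 with Wnt (SE 0.432, edgeR adjusted p = 2.54e-06), by -1.36 with the FZD5 agonist (SE 0.393, edgeR adjusted p = 0.0319) and by -1.88 with the FZD6 agonist (SE 0.431, edgeR adjusted p = 0.0135). These values rest on CHIR 2 alone, at 9.43 CPM, while CHIR 1 and CHIR 3 were at 2.38 and 1.55 CPM, below each FZD5 agonist library. In the fit of all 18 libraries Axin2 did not pass against CHIR with Wnt (-3.73, SE 1.06, edgeR adjusted p = 0.0888), the FZD5 agonist (-0.31, SE 0.937, edgeR adjusted p = 0.932) or the FZD6 agonist (-1.13, SE 0.950, edgeR adjusted p = 0.872). Nkd1 had log2 differences of 2.55 and 1.85 with the agonists there (edgeR adjusted p = 0.0617 and 0.556). The quasi-likelihood test of edgeR called 317, 1 and 1 genes over 18 libraries and 4643, 2367 and 1478 over 14. DESeq2 called 1038, 620 and 66, and limma voom with quality weights 916, 89 and 24. The Wnt count was 50, 34 and 29 (31, 24 and 20 higher) without WNT 1, 2 and 3, 147 without CHIR 1 and 677 without CHIR 3. The FZD5 agonist count was 219 and 131 without CHIR 2 and 3, 2 without FZD5 agonist 2 and 0 without CHIR 1. The FZD6 agonist count was 39 and 21 without CHIR 3 and FZD6 agonist 1 and 0 without CHIR 1, CHIR 2, FZD6 agonist 2 or FZD6 agonist 3.

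Genes that withdrawal had lowered or raised by more than 2-fold at 48 h against CHIR were followed in the ligand groups against 24 h withdrawal, a pair of comparisons that share no library. Of the 178 lowered genes 0 rose, and of the 155 raised genes 0 fell, with Wnt, the FZD5 agonist or the FZD6 agonist over 18 libraries. Only 5, 1 and 0 genes were called against 24 h withdrawal there, none of them lower, so these counts could hardly differ from 0 (independent lists would share 0.0539, 0.0108 and 0 for the lowered genes that rose). Of the raised genes, 3 rose further with Wnt (independent lists would share 0.047). The 178 lowered genes had a median log2 change of -0.64 with Wnt, -0.27 with the FZD5 agonist and 0.02 with the FZD6 agonist, and the 155 raised genes 0.77, 0.49 and 0.17. The limit on the sets moved these medians. With a log2 change beyond 2, the 36 lowered genes had medians of -1.53, -0.40 and 0.40, and the 57 raised genes 1.15, 0.97 and 0.37. Single libraries also moved the medians of the sets beyond 2-fold. Without FZD6 agonist 1, which leaves sets of 237 and 200 genes, those of the FZD6 agonist were -0.25 and 0.41, beside -0.34 and 0.55 for the FZD5 agonist. Over all single omissions the FZD6 agonist medians ran from -0.25 to 0.11 for the lowered and, between FZD6 agonist 2 and FZD6 agonist 1 left out, from 0.08 to 0.41 for the raised genes (0.09 without FZD6 agonist 3, 0.10 and 0.28 without 24 h withdrawal 2 and 3). The FZD5 agonist medians were -0.13 and 0.31 without CHIR 3, and the Wnt median of the raised genes was 0.46 without CHIR 2. Over the 14 libraries the sets, taken against CHIR 2 alone, held 817 lowered and 820 raised genes, with medians of -0.70, -0.05 and 0.05 for the lowered and 0.68, 0.32 and 0.25 for the raised genes with Wnt, the FZD5 agonist and the FZD6 agonist. With Wnt, 0 of the lowered genes rose and 437 fell further (independent lists would share 55.1 and 56.0), and 1 of the raised genes fell and 451 rose further (56.2 and 55.3). With the FZD5 agonist, 3 of the lowered genes rose and 29 fell (19.4 and 15.2), and 15 of the raised genes fell and 132 rose (15.2 and 19.5). With the FZD6 agonist, 0 of the lowered genes rose and 7 fell (4.36 and 1.17), and 2 of the raised genes fell and 32 rose (1.18 and 4.37). A median over single genes here carries no test, and the differences between ligands were not tested.

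**Figure D3:**
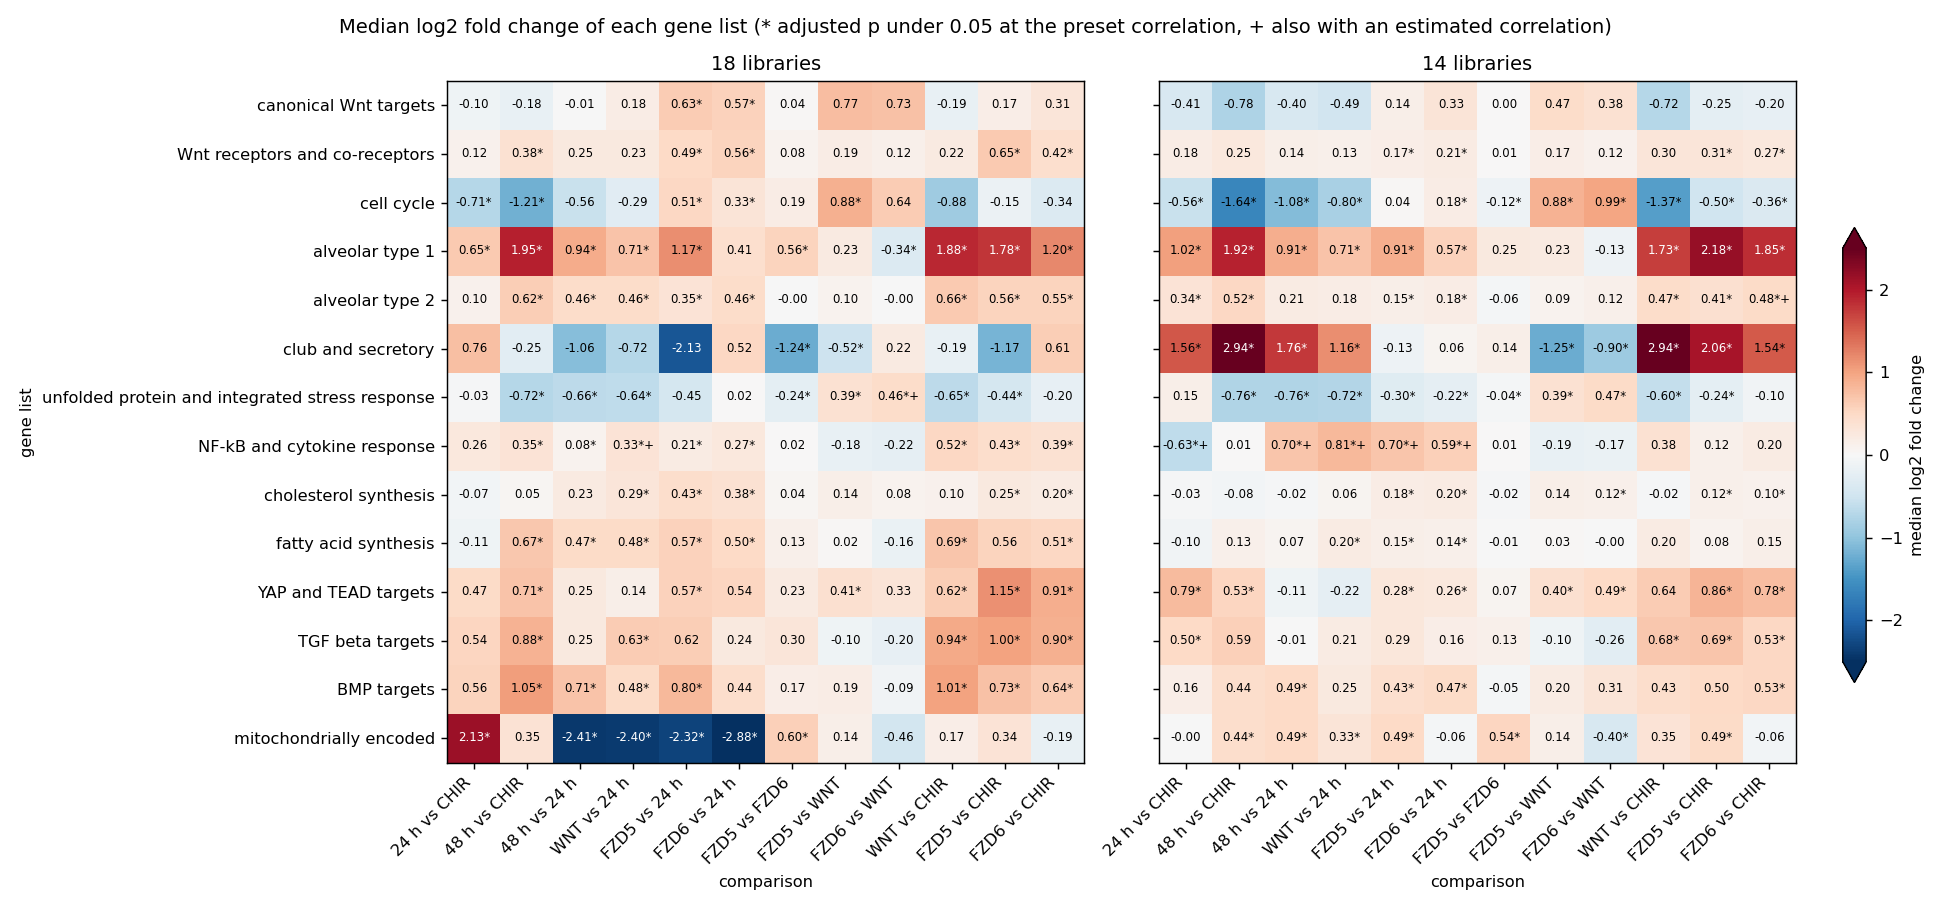
Median log2 fold change of 14 gene lists in the 12 comparisons, over all 18 libraries (left) and over the 14 that remain without CHIR 1, CHIR 3, FZD6 agonist 1 and 24 h withdrawal 2 (right); a star marks a camera adjusted p under 0.05 and a plus the same with an estimated correlation. The mitochondrially encoded list is at -2.41, -2.40, -2.32 and -2.88 against 24 h withdrawal over 18 libraries, and the cell cycle list at 0.88 and 0.99 for the FZD5 and FZD6 agonists against WNT over 14.

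Of the 24 lists tested in 12 comparisons over 18 libraries, 94 calls were made, 2 of which held with an estimated correlation. Splits that mixed the groups of a comparison called lists as well. The real grouping called the most only for 48 h against CHIR (12, highest other 11), the FZD5 agonist against 24 h (12 and 11) and the FZD6 agonist against CHIR (10 and 9). Elsewhere another split called as many or more, such as 8 against 2 for the FZD6 agonist against Wnt. The number of lists called therefore does not set a grouping apart by itself. Most lists called in 1 comparison were also called in others, and whether a list's change differed between comparisons was not tested. Notch targets, FGF and ERK targets, ciliated cell markers, the interferon response, immediate early and heat shock genes and gastric and gut markers were called in none, with lowest camera adjusted p = 0.0561, 0.0574, 0.113, 0.245, 0.113 and 0.210. Wnt receptors were higher with both agonists against 24 h withdrawal (medians 0.49 and 0.56, camera adjusted p = 0.0138 and 0.0398; adjusted p = 0.560 and 0.754 with an estimated correlation). The call for the FZD5 agonist was lost without 24 h withdrawal 2 (adjusted p = 0.170), and that for the FZD6 agonist without 24 h withdrawal 1, 2 or 3 or FZD6 agonist 2 or 3 (highest adjusted p = 0.573). They were also higher than with CHIR with the FZD5 agonist, the FZD6 agonist and at 48 h (medians 0.65, 0.42 and 0.38, camera adjusted p = 0.00556, 0.0040 and 0.0376; adjusted p = 0.463, 0.451 and 0.777 with an estimated correlation). These calls were lost without CHIR 1, that at 48 h also without CHIR 2 or any 1 of the 48 h libraries (highest adjusted p = 0.182, 0.294 and 0.631). Wnt ligands and planar polarity genes were higher than with CHIR at 48 h, with Wnt, with the FZD5 agonist and with the FZD6 agonist (12, 12, 13 and 16 of 16 genes, medians 0.54, 0.41, 0.60 and 0.58, camera adjusted p = 0.0049, 0.00654, 0.0012 and 0.000155; adjusted p = 0.280, 0.352, 0.248 and 0.146 with an estimated correlation). The calls at 48 h and with Wnt were lost without CHIR 1 (adjusted p = 0.0748 and 0.164). The transitional epithelial state list was lower at 48 h than at 24 h (6 genes over the list alone, median -0.47, camera adjusted p = 0.00256; adjusted p = 0.373 with an estimated correlation), a call lost without 24 h withdrawal 1 (adjusted p = 0.109). With the FZD5 agonist the NF-kB and cytokine list was called higher against 24 h withdrawal and against CHIR (medians 0.21 and 0.43, camera adjusted p = 0.0256 and 0.0393; adjusted p = 0.409 and 0.248 with an estimated correlation), while its means were -0.05 and -0.01. The first call was lost without 24 h withdrawal 1 or 24 h withdrawal 3 (highest adjusted p = 0.254), the other without CHIR 3 or FZD5 agonist 3 (highest adjusted p = 0.0984). Markers of basal, neuroendocrine, mesenchymal, haematopoietic and endothelial cells had 3, 3, 4, 3 and 2 tested genes, too few for the test.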

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

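The tests of why libraries stand apart were chosen after the results were seen. The test between the withdrawal times was fixed before.

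For 7 of the genes called between the withdrawal times, the effect of 48 h of withdrawal differed from the effect of 24 h against the same CHIR libraries, tested as the direct contrast of the withdrawal times with edgeR over 18 libraries. The log2 difference was 3.24 for Itih4 (SE 0.509, adjusted p = 0.0280), 2.15 for Itm2a (SE 0.324, adjusted p = 0.0256), 1.68 for Cyp4v3 (SE 0.244, adjusted p = 0.0256), 1.61 for Chil1 (SE 0.270, adjusted p = 0.0482) and 1.53 for Crebrf (SE 0.233, adjusted p = 0.0256). It was 1.43 for Cxcl5 (SE 0.225, adjusted p = 0.0280) and -1.86 for Mettl1 (SE 0.259, adjusted p = 0.0256). Each gene had all 3 libraries of 48 h on 1 side of all 3 of 24 h. The rule for naming required this of all of them but Cxcl5, so it adds no support. Mettl1 alone was called without 24 h withdrawal 1, and none of the 7 without any 1 of the 48 h libraries.

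The share of the library total outside gene counts was 31.3% in 24 h withdrawal 2, against 12.0% to 15.6% in the CHIR control libraries.

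CHIR 1, CHIR 3, FZD6 agonist 1 and 24 h withdrawal 2 stood apart from the other 14 libraries. A different origin of the cells may be a candidate explanation for the last 3. Their highest Xist level was 0.141 CPM against a lowest level of 6.36 CPM in the other 15. These 3 were not all alike. CHIR 3 and FZD6 agonist 1 correlated at 0.983, while 24 h withdrawal 2 reached at most 0.7925 with any library. On the second principal component CHIR 3 and FZD6 agonist 1 lay at -113.1 and -107, and 24 h withdrawal 2 at 19.12. On the first, 24 h withdrawal 2 lay at 288.2. An origin shared by all 3 would leave the distance of 24 h withdrawal 2 from CHIR 3 and FZD6 agonist 1 unexplained. For CHIR 1 its Xist of 22.2 CPM argues against the same origin as those 3, and yet another origin stays open. On the third principal component (12.5% of the variance) CHIR 1 lay at -126.1, CHIR 2 at -43.6 and CHIR 3 at 7.0. There 24 h withdrawal 1 and 3 lay at -13.2 and -10.7 and the 48 h libraries at 25.5 to 30.7. What sets CHIR 1 apart on this component was not tested. Airway cells carried over into the cells of the other 15 would have left the Xist of those cells, so 0.141 CPM argues against that for the 3, and for CHIR 1 the highest of Scgb1a1, Bpifa1, Reg3g and Aqp3 was 0.301 CPM, within the 0.947 CPM reached in the 14. More reads outside genes may add to the distance of 24 h withdrawal 2 (31.3%), but the other 3 reached at most 15.1%, below the 15.6% of the 14, which argues against it for them. An exchange of CHIR 3 with FZD6 agonist 1 cannot be told apart (highest correlation 0.949 with the other's group, 0.943 and 0.952 with their own and 0.983 with each other, against a lowest of 0.963 between any pair of the 14), a single wrong label stays open, and no biological explanation was tested, since the labels describe no difference between these libraries.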

How the results depend on the processing

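The 14 libraries, the pool term for the 3 libraries with low Xist, the quality weights and the 48 h baseline without 4 libraries were chosen after seeing the data; the other settings were fixed before, apart from single libraries left out of the list tests. The cause of each change was not tested, apart from the fewer libraries or groups that some settings use. Scaling factors moved the median of all genes by less than 0.1 in log2 in each comparison. The depth, at least 31509607 counts per library, limits genes near 0.0952 CPM.

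Numbers of genes called follow in the order of the report. DESeq2 called 454, 1237, 565, 374, 145 and 233 genes in the comparisons of 24 h withdrawal with CHIR, 48 h with CHIR, 48 h with 24 h, and Wnt, the FZD5 agonist and the FZD6 agonist with 24 h; it called 30 and 58 for the FZD5 and FZD6 agonists against Wnt and 1038, 620 and 66 for Wnt, FZD5 and FZD6 against CHIR. Over the 14 libraries these counts were 784, 4791, 3136, 2371, 738 and 118, then 1 for FZD5 against FZD6, 2903, 2057, 4643, 2367 and 1478. Quality weights gave 1104, 3289, 2403, 326 and 131 from 48 h with CHIR on, then 2 for FZD5 against FZD6, 3513, 3674, 916, 89 and 24. The pool term gave 1279 for 48 h with CHIR, 75 for 48 h with 24 h, 25 and 2 for Wnt and FZD6 with 24 h, 9 and 32 for FZD5 and FZD6 with Wnt, and 1018, 23 and 6 for Wnt, FZD5 and FZD6 with CHIR. Without the filter 204, 3, 4, 173, 14 and 0 genes were called for 48 h with CHIR, 48 h with 24 h, FZD6 with Wnt, and Wnt, FZD5 and FZD6 with CHIR. Fits of only the compared groups called 129, 0, 0, 0, 1998, 9, 109, 0 and 0 for 48 h with CHIR, 48 h with 24 h, Wnt and FZD5 with 24 h, FZD5 and FZD6 with Wnt, and Wnt, FZD5 and FZD6 with CHIR. The fold of 1.5 left 57, 0, 0, 0, 21 and 0 for 48 h with CHIR, 48 h with 24 h, Wnt and FZD5 with 24 h, and Wnt and FZD6 with CHIR. For FZD5 with 24 h, upper-quartile factors called 0 and the filter of 1 CPM 2. With the 48 h baseline the counts were 0, 0 and 2 for Wnt, FZD5 and FZD6, and without the 4 libraries 0, 2737 and 2118.

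With the replicate number as a block, 257 genes were called for 48 h with CHIR, 2 for 48 h with 24 h, 0 for FZD5 with 24 h, 198 for Wnt with CHIR and 0 for FZD6 with CHIR; no other count moved by over 1.5 times. The numbers gave no sign of pairing the samples. Of 45 same-number pairs, 4 had deviations correlated above 0.1 (median -0.0226, range -0.521 to 0.466). The median was 0.0150 for other numbers, and 5 of 18 libraries correlated best with their own number. The deviations are from group means that include the 4 libraries that stand apart, so they cannot exclude pairing.

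Leaving out each library in turn gave 0 to 8 genes for 24 h with CHIR, 57 to 920 for 48 h with CHIR, 0 to 509 for 48 h with 24 h, and 0 to 21, 0 to 1139 and 0 to 985 for Wnt, FZD5 and FZD6 with 24 h. It gave 0 to 0 for FZD5 with FZD6 and with Wnt, 0 to 2 for FZD6 with Wnt, and 29 to 677, 0 to 219 and 0 to 39 for Wnt, FZD5 and FZD6 with CHIR; the report names the libraries. The number of list calls, 94, was 91 to 108, and 2 with an estimated correlation. Leaving single libraries out of the 14 was not run.

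The 6 counts of withdrawal genes moved back were 0 under the planned settings, apart from 0 to 1 for raised genes lowered by FZD5 or FZD6 without 24 h withdrawal 3. Over the 14 libraries raised genes lowered numbered 1, 15 and 2 for Wnt, FZD5 and FZD6 and lowered genes raised by FZD5 3, and quality weights gave 1 for Wnt. The set from 24 h withdrawal measured against 48 h held 0 genes and gave no value.

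The direction turned in 5 of the called lists and in 3 named genes that were called with all libraries or under the alternative. Turns of genes called in neither were not counted. The mitochondrially encoded median went from 2.13 for 24 h with CHIR to -0.00378 over 14 libraries (single omissions -0.11 to 3.05). It went from -2.41 to 0.489 for 48 h with 24 h (-2.92 to 0.479), from -2.40 to 0.326 for Wnt with 24 h (-2.90 to 0.302), and from -2.32 to 0.495 for FZD5 with 24 h (-2.83 to 0.473). In each of the 4 it turned without 24 h withdrawal 2. Without that library the cell cycle test turned for 24 h with CHIR (median -0.23, omissions -1.18 to -0.23) and FZD6 with 24 h (-0.181, omissions -0.181 to 0.752). The hypoxia test turned for FZD5 with 24 h over 14 libraries (median 0.0233). For FZD5 with FZD6 it turned over 14 libraries (-0.0133), with the pool term (-0.0515) and without FZD6 agonist 1 (omissions -0.0190 to 0.507). There p53 targets turned without FZD6 agonist 1 (omissions -0.456 to -0.0373), as did the club and secretory list (-1.74 to 0; -0.0119 with the pool term). In these the test against other genes turned, and a median can keep its sign. For FZD6 with 24 h, Nfkbia went to 0.67 over 14 libraries, Padi2 to -1.53 and -1.37 with quality weights, and Ly6a to -1.30 and -1.27.

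Of 1034 values of called lists under the alternatives, 757 kept direction and call and 260 lost the call. Of 2862 values of named genes, 2387 did not change between called and not called, 243 lost the call and 227 gained one. The 2387 include genes called neither with all libraries nor under the alternative. These had no call to keep, and turns in their direction were not counted.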

Other observations

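The tests of explanations in this part, their limits and the counts of splits were recorded after the results were seen. The values over 14 libraries come from an alternative chosen after seeing the data.

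Etv5, an ETS factor that maintains the alveolar type 2 state, was lower at 48 h and with Wnt than at 24 h over the 14 libraries. It fell by 0.97 (SE 0.0777, edgeR adjusted p = 1.89e-06) from 284 ± 14.9 CPM at 24 h (n = 2) to 144 ± 6.42 CPM at 48 h (n = 3). It fell by 0.92 (SE 0.0777, edgeR adjusted p = 3.82e-06) to 150 ± 2.71 CPM with Wnt. With the FZD5 and FZD6 agonists it was at 298 ± 28.7 CPM (n = 3) and 309 ± 7.26 CPM (n = 2). It was higher than with Wnt by 0.98 (SE 0.0710, edgeR adjusted p = 6.06e-07) and 1.04 (SE 0.0776, edgeR adjusted p = 1.27e-06). Over all 18 libraries none of these differences in Etv5 was called. Wnt7a, a Wnt ligand, was higher after 24 h of withdrawal than in CHIR 2 by 1.88 (SE 0.281, edgeR adjusted p = 0.0020), with LGK974 in both. The club cell gene Cyp2f2 was lower with the FZD5 agonist than with Wnt by -1.25 (SE 0.352, edgeR adjusted p = 0.0439) and with the FZD6 agonist by -1.54 (SE 0.409, edgeR adjusted p = 0.0447).

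Between the WNT and 48 h withdrawal libraries 0 genes were called by edgeR over 18 or 14 libraries, with 35 and 1344 at an unadjusted p under 0.05. A candidate explanation is that Wnt targets did not respond to this ligand at the sampled time. Axin2 differed by -0.40 over 14 libraries, with a range of 2 SE from -1.30 to 0.50, while it was higher with the FZD5 agonist than at 48 h by 3.01, with a lower bound of 2.26. A similar time without CHIR in both groups cannot be told apart from this, because 0 called genes fit it too and the labels do not give that time. The same libraries deposited again is argued against by a chi-square per degree of freedom of at least 14.7 in all 9 pairs.

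The FZD5 and FZD6 agonist libraries differed from the WNT libraries by 2903 and 2057 genes over 14 libraries. If time without CHIR were the whole cause, each gene should stay between its CHIR, 24 h and 48 h levels. With the FZD5 agonist 71 genes lay outside them (41 above, such as Egfr, and 30 below, such as Cyc1 and Uqcrq of the respiratory chain), among 738 called against 24 h, and with the FZD6 agonist 18 (16 and 2) among 118. For neither agonist can time alone be excluded, since 1 library sets the CHIR level and peaks between sampled times and times under 24 h are not covered. As a part, time cannot be told apart from a response to the agonists that opposes withdrawal: of 1271 genes called both for the FZD5 agonist against Wnt and for 24 h against 48 h, 1230 went the same way (262 for independent lists), and for the FZD6 agonist 1126 of 1137 (186), with r = 0.26 and 0.334 across all genes, which are not independent replicates.

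Each comparison has 10 splits of its 6 libraries into groups of 3, too few for a share under 0.05. For the count of genes, the splits as large as the real one numbered 10 for 24 h withdrawal against CHIR (0 genes, highest other 2055), 1 for 48 h against CHIR (427, highest other 0), 1 for 48 h against 24 h (8 and 0), 1 for Wnt (5 and 0) and 1 for the FZD5 agonist (1 and 0) against 24 h. They numbered 10 for the FZD6 agonist against 24 h, the FZD5 against the FZD6 agonist, and either against Wnt, each with 0 genes and a highest other of 0. Against CHIR they numbered 1 for Wnt (317 and 0), 1 for the FZD5 agonist (1 and 0) and 2 for the FZD6 agonist (1 and 381). The split with 381 genes set FZD6 agonist 1, CHIR 1 and CHIR 3 against the other 3. The split with 2055 genes set CHIR 2, 24 h withdrawal 1 and 24 h withdrawal 3 against CHIR 1, CHIR 3 and 24 h withdrawal 2, and the large counts of both point to a structure of the libraries. For the number of lists called, in the same order of comparisons, the splits numbered 8 (3 lists, highest other 14), 1 (12 and 11), 4 (8 and 8), 2 (9 and 9), 1 (12 and 11), 5 (8 and 14), 8 (6 and 9), 7 (4 and 6), 10 (2 and 8), 4 (9 and 11), 3 (11 and 11) and 1 (10 and 9). For the 6 counts of withdrawal genes moved back by a ligand they numbered 10, with 0 and 0 in each.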
